A study of Rattus norvegicus with 29 samples.

How the data were processed

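Gene expression was measured in the nucleus accumbens shell of alcohol-preferring (P) rats, a line bred selectively for voluntary ethanol intake, on 29 Affymetrix rat arrays. The labels placed 10 samples in a continuous ethanol group, 10 in a limited access group and 9 in a water group. Total RNA was extracted with Trizol and purified with RNeasy columns, and biotinylated cRNA was hybridised, per the labels' protocols. The deposited values are log2 expression values made by the authors with RMA (robust multi-array average, which corrects background, quantile normalizes arrays and summarises the probes of a probe set), per the submitters' processing notes. The log base was read from the values, which lay between 4.04 and 16.0. The RMA software and its version, the array batches and the hybridisation dates were not given in the sources used here. Because RMA makes the distributions of arrays nearly equal, a change of all transcripts together would not be seen in these values.

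The table held 31099 probe sets, of which 57 control probe sets were left out of the tests. A platform table paired 20832 probe sets with 1 gene symbol, 436 with several and 9831 with none; the last are called unnamed here, and no gene was named from a probe set with several symbols. Symbols of 20764 probe sets were matched by gene ID to a table of rat genes of assembly GRCr8, which was used for names only. The dimmest 30 percent of probe sets by mean over all arrays were left out, which removed those with a mean at or below 6.86, and 21729 probe sets were tested. Of these, 15759 (72.5%) had 1 symbol and stood for 11328 genes.

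All 29 arrays entered 1 model with group as its only factor, fitted with lmFit and eBayes of limma 3.58.1 (statmod 1.5.0) in R 4.3.3. The 3 group differences were tested two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 21729 probe sets, with a threshold of 0.05. A test over the 3 groups used the moderated F statistic. Changes are differences of group means on the log2 scale with their standard error (SE), and single values are given with the standard deviation (SD) between arrays. The number of arrays showing a direction is the number in the first group that lay on that side of the mean of the second. Adjusted p-values of genes are from limma throughout. The groups, tests, gene lists, naming rule and the alternatives named next were fixed before the data were examined.

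Genes were named by a rule. In each comparison these were the 10 genes that rose and the 10 that fell most among those past the threshold, or, where fewer than 5 passed in a direction, those that passed and the genes of smallest p until 5 were reached. Up to 4 members of smallest p were named from each list, and Drd1, Drd2, Penk, Pdyn, Tac1, Fos and Bdnf whatever their p. Idi1, which passed outside the largest changes, entered as an example of its list. Unnamed probe sets given with values were chosen after those were seen. The 33 fixed gene lists comprised 22 of pathways or gene classes and 11 of cell type markers. A gene was represented in a list by its brightest tested probe set. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, with camera at an estimated correlation, with fry and with an exact permutation test of the mean of a list per array, and p-values were adjusted over the 33 lists. The exact test was added after seeing the data. Marker scores of an array are means over the markers of their log2 deviation from the mean of all arrays. Array measures were compared by exact two-sided permutation tests.

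The alternatives set in advance were no filter, a stricter filter on dim probe sets, quantile normalization applied again, centring on array medians, a trended and robust prior, array weights, the replicate number as a block, a covariate for the 3 prime to 5 prime signal of control transcripts, leaving out the array least like its group (water replicate 9), 1 probe set per gene, a fit of only the groups compared and, for lists, the mean of all probe sets of a gene. Covariates for the SD of the array, for cortical markers and for 16 leptomeningeal markers, leaving out arrays with an extreme leptomeningeal score, leaving out or blocking 5 arrays that lay apart on the second principal component, and leaving out each array in turn were chosen after seeing the data.

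The correlation of the changes of both ethanol groups against the shared water arrays was set beside 100 simulated unchanged groups, and computed again with the water arrays split into 5 and 4. In each split the 33 probe sets of smallest p against the 5 were chosen anew, so that the arrays used for choosing them were not those of the limited access change. The fit was tested on simulated data with the spread of these arrays. Probe sets varied independently there, and 67, 67 and 66 of them were changed by 0.2, 0.4 and 0.8. For continuous ethanol against water it recovered 46.3% of probe sets changed by 0.2, 92.5% of those changed by 0.4 and 98.5% of those changed by 0.8, with 12 false calls among 170. For limited access against water the shares were 40.3%, 91.0% and 100%, and for limited against continuous 58.2%, 95.5% and 97.0%. The more probe sets change, the easier the adjusted threshold is to pass, so these shares need not hold where fewer change. Simulated lists of independent genes gave 0 camera calls without a shift and 1 where a single list was shifted by 0.2. Since genes of real arrays can vary together, this does not show how often camera calls lists by chance. Other splits of the real arrays gave medians of 6, 4 and 5 called lists for continuous minus water, limited minus water and limited minus continuous. The number of arrays limits the precision, and the median SE of a change was 0.05. Permutation tests and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.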

Results

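The nucleus accumbens shell, a part of the ventral striatum that receives dense dopamine input and takes part in reward, was profiled in P rats after chronic ethanol. The groups were continuous ethanol (n = 10), limited access to ethanol (n = 10) and water (n = 9). The design text names 10 samples for each group, so a water sample of that design was not analysed here. The medians of the arrays lay between 8.17 and 8.21 on the log2 scale, and correlations between pairs of arrays over all probe sets lay between 0.986 and 0.998, with 0 pairs of identical arrays. Over the tested probe sets only, water replicate 9 had the lowest median correlation with its own group, 0.979. The labels do not state that each sample came from a separate animal, so p-values measure the spread between these samples, which may in part be technical. The number of arrays limits the precision of each change.

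The SD of the array, the beta-actin and GAPDH measures, the median correlation with all arrays and the leptomeningeal score were compared between groups. None of these passed after adjustment over them. The median correlation of an array with its own group was not adjusted with them. It was 0.989 ± 0.004 (SD) in water, 0.993 ± 0.003 in continuous (exact permutation p = 0.00299) and 0.993 ± 0.003 in limited arrays (against water, exact p = 0.00550), so its mean was lowest in water. The correlations were not computed again for each regrouping, and arrays of a group share pairs. These p-values therefore cannot decide whether water arrays were less alike. The SD of all values of an array was 2.18 ± 0.01 (SD) in the continuous group and 2.16 ± 0.02 in the water group (exact permutation p = 0.0157, adjusted p = 0.0547). The 3 prime minus 5 prime signal of beta-actin, a measure of RNA quality and labelling, was 1.27 ± 0.08 in the continuous group, 1.20 ± 0.05 in the water group (exact p = 0.0219, adjusted p = 0.0547) and 1.17 ± 0.09 in the limited group (against continuous, exact p = 0.0146, adjusted p = 0.0732). The same measure of GAPDH had the opposite sign for continuous minus water (-0.01, exact p = 0.603), and the mean of both gave an exact p of 0.172 there. That mean was 0.57 ± 0.06 in continuous, 0.53 ± 0.03 in water and 0.50 ± 0.05 in limited arrays. Leptomeningeal markers such as Igf2, Ogn and Mgp had a mean deviation of -0.11 ± 0.58 in the continuous, -0.06 ± 0.34 in the limited and 0.20 ± 0.40 in the water arrays (continuous against water, exact p = 0.208). On the second principal component, with 16.5% of the variance, 5 arrays lay apart, at scores from -22.2 to -15.6 against -3.30 to 20.2 for the rest. These were water replicates 2, 5 and 6 and limited replicates 6 and 7, with 0 continuous arrays among them. Scores on that component differed between continuous and water arrays at an exact permutation p of 0.0360, which was not adjusted.

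**Figure D1:**
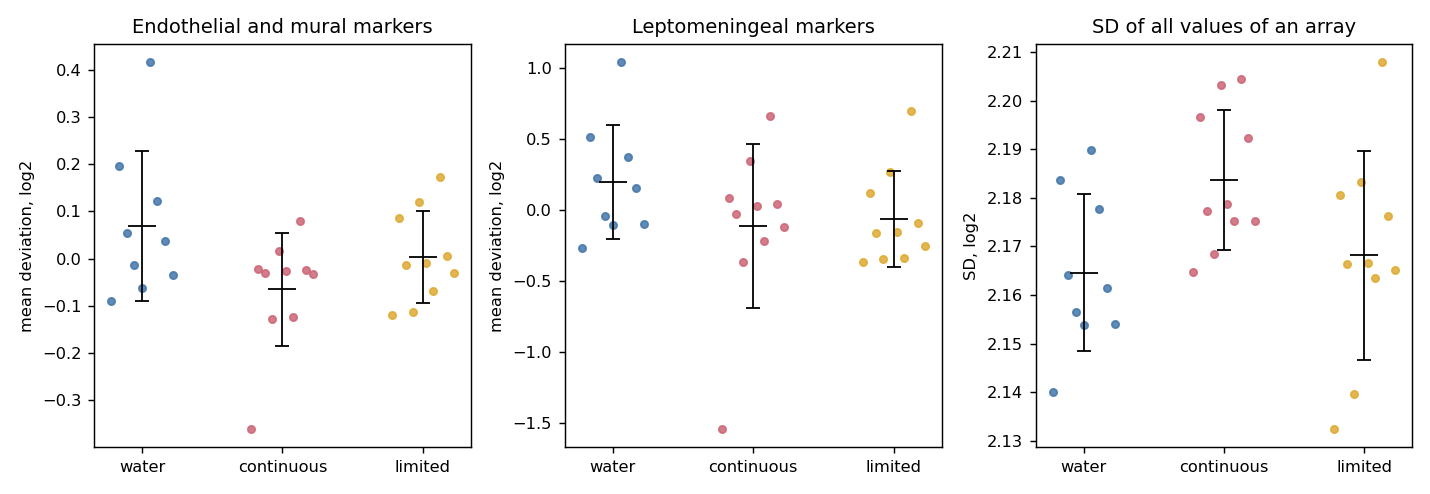
Each dot is 1 array, by group, for the mean log2 deviation of endothelial and mural markers, that of leptomeningeal markers, and the SD of all log2 values of the array, with group means and SD as black bars. The continuous and water groups overlapped in all 3 measures, and continuous replicate 3 was lowest in both marker scores.

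The comparison of continuous ethanol with water asked which transcripts of the accumbens shell differed after continuous access to ethanol. Of 29 measured immediate early genes, which neurons transcribe rapidly after activation, 6 rose in the continuous group and 23 did not pass, each judged on its brightest probe set. Jun and Homer1 were among the 23, although dimmer probe sets of both passed, as given below. The list as a whole had a median of 0.09 (adjusted p = 0.609 with an estimated correlation, exact permutation adjusted p = 0.0847). Fos, which encodes a subunit of the AP-1 transcription factor, rose from 10.26 ± 0.27 (SD, n = 9) in water to 11.04 ± 0.27 (SD, n = 10), a log2 change of 0.79 ± 0.12 (SE, adjusted p = 0.00120), with 10 of 10 arrays above the water mean. Nr4a1, an orphan nuclear receptor, rose by 0.70 ± 0.09 (adjusted p = 1.05e-04, 10 of 10 arrays), and Arc, which encodes a synaptic protein that regulates AMPA receptor trafficking, rose by 0.61 ± 0.11 (adjusted p = 0.0131, 10 of 10 arrays). Angptl4, which encodes an inhibitor of lipoprotein lipase, fell by 0.31 ± 0.06 (adjusted p = 0.0165, 10 of 10 arrays), and Adgrl4, an adhesion receptor of endothelial cells, fell by 0.37 ± 0.07 (adjusted p = 0.0143, 10 of 10 arrays).

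In all, 33 probe sets passed the threshold, 19 higher and 14 lower in the continuous group, with absolute changes from 0.18 to 0.79. They stood for 15 genes that rose and 6 that fell, Homer1 being counted in both. The other 3 higher and 8 lower probe sets had no single symbol. Dusp1, a MAP kinase phosphatase, rose by 0.50 ± 0.08 (adjusted p = 0.00245, 10 of 10 arrays) on its brighter probe set and by 0.50 ± 0.10 (adjusted p = 0.0257, 9 of 10 arrays) on the other. The transcription factor gene Junb rose by 0.34 ± 0.06 (adjusted p = 0.00506, 10 of 10 arrays), and Gadd45g, a growth arrest and DNA damage gene, rose by 0.37 ± 0.05 (adjusted p = 1.09e-04, 10 of 10 arrays). Ier2 rose by 0.41 ± 0.07 (adjusted p = 0.00821, 10 of 10 arrays). Jun rose by 0.29 ± 0.06 (adjusted p = 0.0179, 10 of 10 arrays) on 1 probe set, while its other probe sets had changes of 0.14 and 0.20 that did not pass. A further Fos probe set, with a water mean of 7.07, had a change of -0.01. Tgif1, a repressor of TGF-beta signalling, rose by 0.28 ± 0.06 (adjusted p = 0.0235), a call lost under 6 of 14 alternatives. Psmc6, a subunit of the proteasome, rose by 0.27 ± 0.06 (adjusted p = 0.0379), a call lost under 11 of 15 alternatives. Among the genes that fell, Lims2 changed by -0.30 ± 0.06 (adjusted p = 0.0131), Slc2a1, the glucose transporter of the blood-brain barrier, by -0.21 ± 0.05 (adjusted p = 0.0492) and Nat8f3 by -0.21 ± 0.04 (adjusted p = 0.0318), each lower in 10 of 10 arrays. Their calls were lost under 5, 10 and 7 of 15 alternatives in that order, those of Adgrl4 and Angptl4 under 5 and 4, those of Jun and the dimmer Dusp1 probe set under 4 each, and that of Ier2 under 1. The 3 unnamed probe sets with the largest decreases, singled out after their values were seen, fell by 0.74 ± 0.10, 0.70 ± 0.09 and 0.64 ± 0.08 (adjusted p = 1.05e-04, 5.60e-05 and 5.45e-05, 10 of 10 arrays each).

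**Figure D2:**
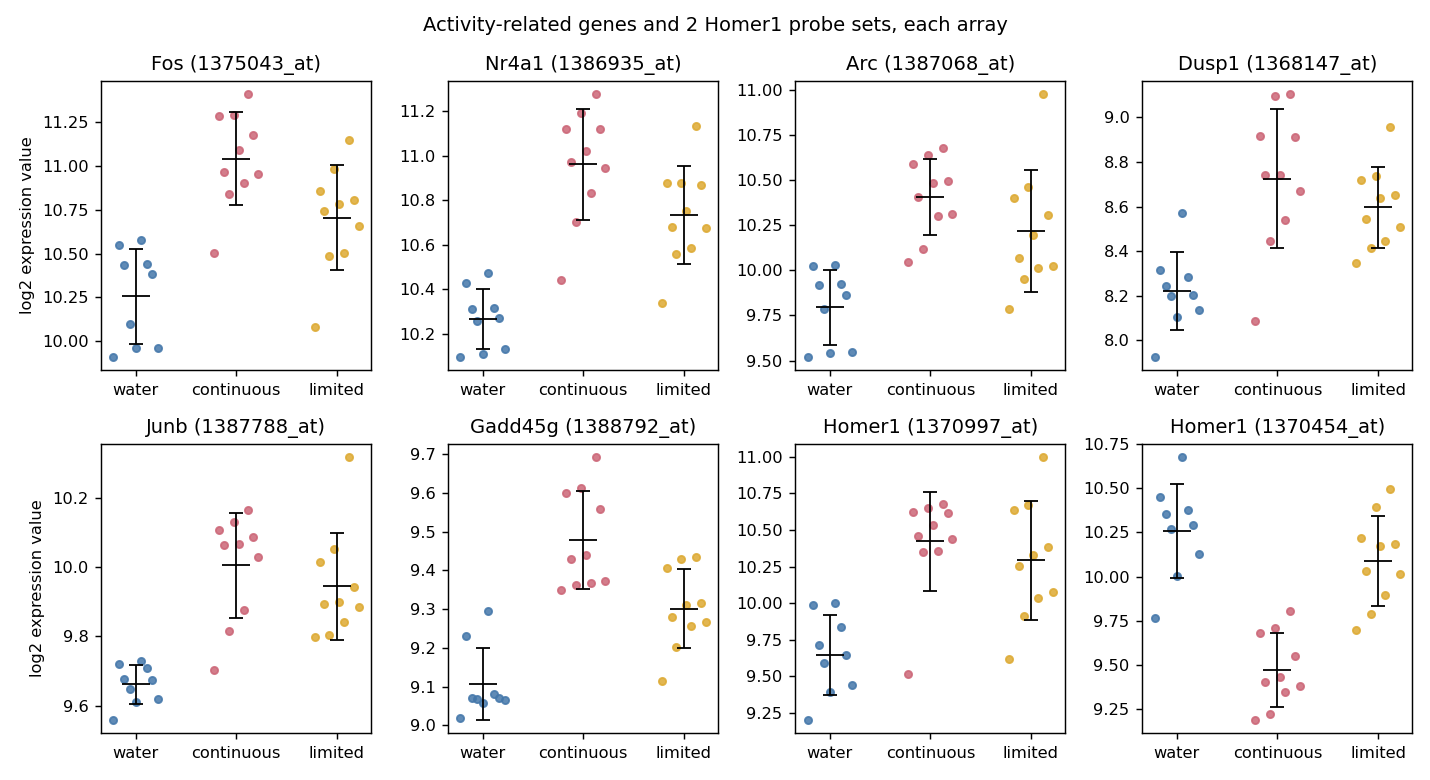
Log2 expression values of each array are plotted by group for 6 genes that rose with continuous ethanol and for 2 probe sets of Homer1, with group means and SD as black bars. Fos was 10.26 in water, 11.04 in continuous and 10.71 in limited arrays, and the Homer1 probe set that fell was 10.26, 9.47 and 10.09 in the same order.

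Homer1 encodes a postsynaptic scaffold and has long constitutive transcripts and a short transcript induced by activity. Its probe sets moved apart. The first of them rose by 0.78 ± 0.15 (adjusted p = 0.0169, 9 of 10 arrays), from 9.65 ± 0.27 to 10.42 ± 0.34 (SD). The second fell by 0.78 ± 0.11 (adjusted p = 1.14e-04, 10 of 10 arrays), from 10.26 ± 0.27 to 9.47 ± 0.21. The remaining 3 Homer1 probe sets had changes of -0.02, -0.01 and -0.00 (adjusted p = 0.877, 0.971 and 0.990). Without water replicate 5 the rise of the first did not pass (adjusted p = 0.0527), and it was lost under 3 of 15 alternatives.

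The 6 immediate early genes that rose were Nr4a1, Fos, Dusp1, Junb, Ier2 and Arc, 0 fell, and adjusted over the list alone 10 rose. Camera gave the list an adjusted p of 1.05e-06 with the preset correlation, against adjusted p = 0.609 with an estimated correlation. Of 33 proteasome genes 0 passed on the probe sets that stood for them, and adjusted over the list alone 5 rose, among them Psma4 (0.13 ± 0.03) and Psmd12 (0.16 ± 0.05). The median of the proteasome list was 0.05 (adjusted p = 0.609 with an estimated correlation). In the cholesterol list, 1 of 32 members rose, Idi1, an isomerase of the mevalonate pathway (0.18 ± 0.04, adjusted p = 0.0302, a call lost under 7 of 15 alternatives), and adjusted over the list alone Insig1 (0.11 ± 0.03) rose too, which made 2. The list median was 0.06 (adjusted p = 0.609 with an estimated correlation). Of 64 genes of oxidative phosphorylation 0 passed, over all probe sets or adjusted over the list alone, with a median of 0.03 (adjusted p = 0.811 with an estimated correlation) and Ndufa4 at 0.09 ± 0.03.

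Of 19 endothelial and mural markers 0 passed over all probe sets, and adjusted over the list alone 2 fell, the tight junction gene Cldn5 (-0.21 ± 0.06) and Esam (-0.24 ± 0.06). Their median was -0.15 (adjusted p = 0.609 with an estimated correlation), with the leptomeningeal and beta-actin measures of these arrays as given above, and it was -0.04 without the 5 arrays of extreme leptomeningeal score (camera adjusted p = 0.101). It was -0.08 with leptomeningeal markers or the SD of the array as a covariate, -0.07 with array weights or without the 5 arrays apart on the second component, and -0.10 with those as a block. Of 15 medium spiny neuron markers 0 passed and 2 fell adjusted over the list alone, Rasd2 (-0.23 ± 0.06) and Rgs9 (-0.20 ± 0.06), both of which modulate dopamine receptor signalling. The same 2 fell among 34 genes of dopamine and cAMP signalling. The medians were -0.05 (adjusted p = 0.811 with an estimated correlation) and -0.02 (adjusted p = 0.695 with an estimated correlation). The receptor genes Drd1 and Drd2 had changes of -0.04 ± 0.06 and -0.16 ± 0.06 (adjusted p = 0.728 and 0.218). Those of the neuropeptide genes Penk, Pdyn and Tac1 were -0.04, -0.05 and -0.01, and that of Bdnf was -0.04. Of 22 glucocorticoid-responsive genes, Dusp1 rose, Angptl4 fell and 20 did not pass; adjusted over the list alone 1 rose and 5 fell, including the glucocorticoid receptor chaperone Fkbp5 (-0.24 ± 0.06) and Tsc22d3 (-0.14 ± 0.04). The list median was -0.04 (adjusted p = 0.695 with an estimated correlation). Of 49 chaperone genes 0 passed, with a median of -0.01 (adjusted p = 0.695 with an estimated correlation) and Hspa5 at -0.14 ± 0.04.

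Camera with the preset correlation called 9 of the 33 lists, 4 up and 5 down, those described above, while 0 held with an estimated correlation. Fry, which tests whether the genes of a list move one way on balance, called 3, the immediate early (adjusted p = 0.0263), cholesterol (0.0263) and proteasome (0.0467) lists, and the exact permutation test of list means called 0, with 5 at an unadjusted p under 0.05. In 8 lists the median, the mean and the test differed in sign; none of these was called. The count of 33 probe sets was 20 with 1 probe set per gene, where probe sets without a single symbol and dimmer ones of a gene were not tested. As covariates, beta-actin and GAPDH quality gave 23 and the SD of the array 11. The count was 21 without the arrays of extreme leptomeningeal score, 12 without the 5 arrays apart on the second component and 14 with those as a block. It was 18 without water replicate 5, 59 without water replicate 8, 94 without water replicate 4 and 66 without limited replicate 6.

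**Figure D3:**
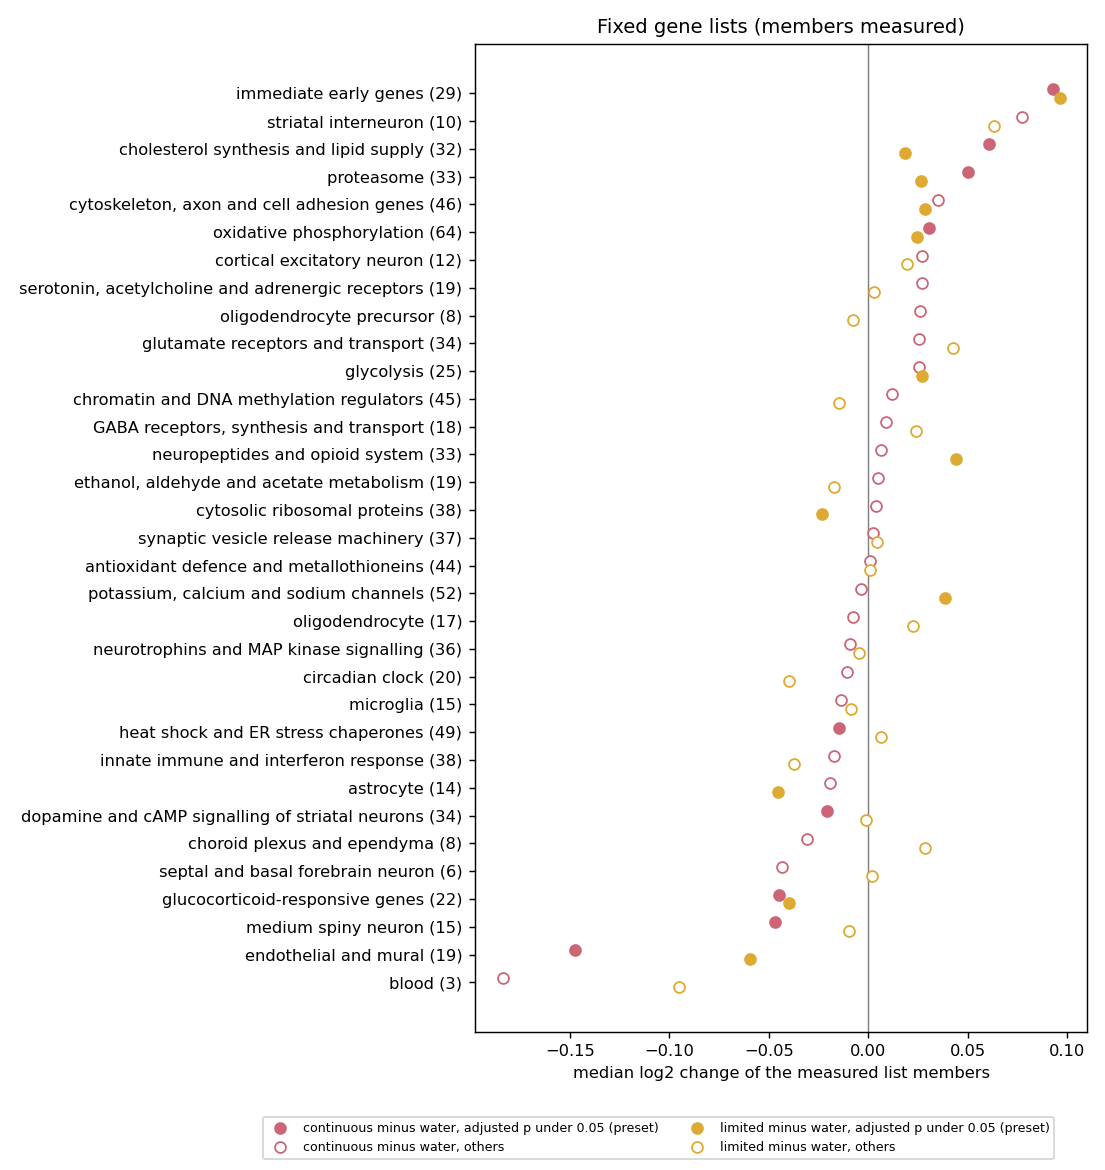
For each fixed list the median log2 change of its measured members is plotted for continuous minus water and limited minus water, with filled dots where camera with the preset correlation gave an adjusted p under 0.05. With an estimated correlation 0 of these calls held. The immediate early genes lay at 0.09 and 0.10, and the endothelial and mural markers at -0.15 and -0.06.

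The comparison of limited access with water asked the same of rats whose access to ethanol was limited. No gene passed the threshold, and Nr4a1 and Junb were among the genes of smallest p. Nr4a1 was 10.27 ± 0.13 (SD, n = 9) in water and 10.73 ± 0.22 (SD, n = 10) with limited access, a difference of 0.47 ± 0.09 (SE, adjusted p = 0.234, 10 of 10 arrays). Junb had a difference of 0.28 ± 0.06 (adjusted p = 0.316, 10 of 10 arrays), Fos of 0.45 ± 0.12 (adjusted p = 0.928, 9 of 10 arrays), Arc of 0.42 ± 0.11 (adjusted p = 0.928, 9 of 10 arrays) and Gadd45g of 0.20 ± 0.05 (adjusted p = 0.841, 10 of 10 arrays). The Homer1 probe set that rose with continuous ethanol differed by 0.65 ± 0.15 (adjusted p = 0.581, 9 of 10 arrays) and the Homer1 probe set that fell by -0.17 ± 0.11 (adjusted p = 0.972, 8 of 10 arrays).

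Limma called 0 of the 21729 probe sets in this comparison, with 965 (4.44%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.234. Among genes with lower values, Nat8f3 had a difference of -0.22 ± 0.04 (adjusted p = 0.234, 10 of 10 arrays), Lims2 of -0.26 ± 0.06 (adjusted p = 0.394), Rps6ka4 of -0.17 ± 0.04 (adjusted p = 0.841), the caveolar protein gene Cav2 of -0.29 ± 0.08 (adjusted p = 0.841) and Fam118b of -0.16 ± 0.04 (adjusted p = 0.928). Drd1, Drd2 and Penk differed by 0.01, -0.10 and -0.00, and Pdyn, Tac1 and Bdnf by 0.03, 0.01 and 0.03. Of the 29 immediate early genes 0 passed over all probe sets and 6 rose adjusted over the list alone; their median was 0.10 (camera adjusted p = 8.25e-12, adjusted p = 0.248 with an estimated correlation). Camera with the preset correlation called 12 lists. The others with positive medians were neuropeptides (0.04), ion channels (0.04), glycolysis (0.03), the cytoskeleton (0.03), the proteasome (0.03), oxidative phosphorylation (0.02) and cholesterol synthesis (0.02). Those with negative medians were endothelial and mural (-0.06), astrocyte (-0.05), glucocorticoid-responsive (-0.04) and ribosomal protein genes (-0.02). With an estimated correlation 0 held, with a smallest adjusted p of 0.248, fry called 0 and the exact test of list means called 0, with 4 at an unadjusted p under 0.05. In 3 lists the median, the mean and the test differed in sign. With array weights 1 probe set passed.

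The comparison of limited with continuous access asked whether the schedules differed from each other. The 1 probe set past the threshold was the Homer1 probe set that had fallen with continuous ethanol, which rose by 0.62 ± 0.10 (SE, adjusted p = 0.0340, 10 of 10 arrays), from 9.47 ± 0.21 (SD, n = 10) with continuous to 10.09 ± 0.25 (SD, n = 10) with limited access. The Homer1 probe set that rose with continuous ethanol differed by -0.13 ± 0.15 (adjusted p = 0.802). Adgrl4 differed by 0.27 ± 0.07, Nbeal2 by 0.20 ± 0.05, Crb3 by 0.20 ± 0.05 and Rnf215 by 0.17 ± 0.05 (adjusted p = 0.526 each). Among lower values, Fam53a differed by -0.20 ± 0.04 (adjusted p = 0.138), the integrin gene Itgav by -0.26 ± 0.06 (adjusted p = 0.413) and Lhfpl2, the cold-inducible Rbm3 and the poly(A) polymerase gene Tent2 by -0.27 ± 0.07, -0.23 ± 0.06 and -0.30 ± 0.07 (adjusted p = 0.526 each). Fos differed by -0.34 ± 0.12 (adjusted p = 0.526, 9 of 10 arrays), Drd1, Drd2 and Penk by 0.06, 0.06 and 0.04, and Pdyn, Tac1 and Bdnf by 0.07, 0.02 and 0.06. At an unadjusted p under 0.05 there were 2022 probe sets (9.31%).

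Camera with the preset correlation called 6 lists in this comparison, and 0 members of any list passed on the probe sets that stood for them. The called Homer1 probe set was not among those. Medians were 0.08 for endothelial and mural markers, 0.03 for dopamine and cAMP signalling, 0.03 for chaperones, 0.02 for ion channels, -0.02 for ribosomal proteins and -0.03 for the proteasome. With an estimated correlation 0 held, with a smallest adjusted p of 0.757, fry called 0 and the exact test of list means called 0, with 2 at an unadjusted p under 0.05. In 8 lists the median, the mean and the test differed in sign. The call of Homer1 was lost under 5 of 15 alternatives, while its change stayed between 0.55 and 0.72. With 1 probe set per gene the count of probe sets was 0, but there the called Homer1 probe set was not tested. A brighter one stood for the gene, so that loss was fixed by the rule. Among other alternatives the count was 0 with, for example, the SD of the array or beta-actin and GAPDH quality as a covariate. The count was also 0 with the 5 arrays apart left out or as a block, and 2 with cortical or leptomeningeal markers as a covariate. It was 0 without continuous replicate 1, 2, 4, 6, 8, 9 or 10, limited replicate 3, 4, 6, 7 or 10, or water replicate 3 or 4, it was 2 without continuous replicate 3 or limited replicate 1 or 5, and it was 3 without limited replicate 8.

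Over the 3 groups together, 18 probe sets differed (smallest adjusted p = 2.80e-04), a count of 10 without continuous replicate 8 or water replicate 6, of 11 without continuous replicate 3 or water replicate 5, and of 10 with the SD of the array as a covariate. All 33 probe sets called with continuous ethanol, Fos, Nr4a1, Arc and Homer1 among them, had the same sign with limited access, and 32 had a smaller change there, with medians of 0.37 and 0.20 in the direction of the call. They were selected for passing with continuous ethanol, and that selection alone makes smaller changes in the other comparison likely. At an unadjusted p under 0.05 were 27 of them in limited minus water and 19 in limited minus continuous. Each of these comparisons shares a group with the one used for selection, which tilts both counts upward. The comparisons of continuous and of limited access with water share the water arrays, which also tilts the signs toward agreement. With the water arrays split into 5 and 4, the 33 probe sets of smallest p for continuous ethanol were chosen anew in each split, against the 5, and their change with limited access was taken against the 4. Of these newly chosen sets, which need not be the 33 called, a median of 27 (14 to 33 over 100 splits) had the same sign with limited access, and the median change there was 0.11. Across the 21729 probe sets, which are not independent replicates, the changes of both schedules correlated at r = 0.609, against a mean of 0.514 (0.0202 to 0.811) in simulated unchanged groups and a median of 0.0670 with split water arrays. The covariance was 0.00413, within the simulated range (mean 0.00287, SD 0.00140, 8.31e-05 to 0.00843), and 6.72e-04 with split water arrays. Of all tested probe sets 70.2% had the same sign with both schedules. That share had a mean of 67.5% (52.5% to 81.7%) in simulated unchanged groups and a median of 54.8% with split water arrays.

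**Figure D4:**
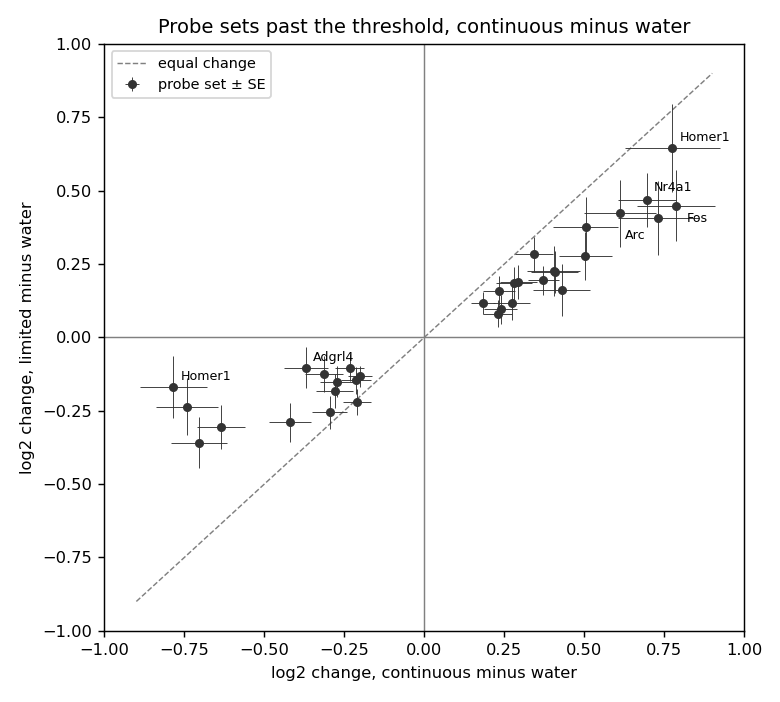
The log2 change of limited minus water is plotted against that of continuous minus water for the 33 probe sets called with continuous ethanol, with SE as bars and a dashed line of equal change. All 33 had the same sign in both comparisons, and 32 had a smaller change with limited access. The 33 were selected on continuous minus water, and both comparisons share the water arrays. That selection alone tilts the changes with limited access toward the same sign.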

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

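The tests of explanations and the counts of splits given here were chosen only after the results had been seen, while the check for samples far from their group was planned. The splits were drawn again when another test was added, and both draws led to the same statements on chance. The rule for the endothelial and mural list was made stricter after its values were seen, and a laxer rule tried for Homer1 was not kept. That check covered 165 groups of values and found 20 with a sample far from the others, where chance alone gives about 1 in 20 groups, or 8.25. Numbers in parentheses are the gap to the nearest array as a share of the range of the group.

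Among single genes, Junb was 10.32 in limited replicate 6 against a median of 9.89 in the others (0.512), and the Homer1 probe set that rose was 9.52 in continuous replicate 7 against 10.53 (0.719). Water replicate 2 was low in genes of dopamine and cAMP signalling (0.675), GABA (0.551), neuropeptides (0.747), medium spiny neurons (0.586) and striatal interneurons (0.582). Continuous replicate 7 was high in antioxidant (0.554), chaperone (0.656), oxidative phosphorylation (0.489), ribosomal protein (0.511), astrocyte (0.587) and microglia genes (0.586) and low in serotonin, acetylcholine and adrenergic receptors (0.602). Continuous replicate 3 was low in GABA genes (0.492) and in endothelial and mural markers (0.526). Continuous replicate 10 was low in glycolysis genes (0.4934). Limited replicate 9 was high in ethanol metabolism (0.549), antioxidant (0.487) and choroid plexus genes (0.695), the last with a score of 1.29 against a median of -0.17.

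Of 29 immediate early genes 6 rose with continuous ethanol, with a median change of 0.56 over those 6, which were selected for passing. Over all 29 the median was 0.09, Egr3 (-0.13) and Ier3 (-0.21) had negative changes, and the list call was lost with an estimated correlation (adjusted p = 0.609). With cortical markers as a covariate the median was 0.54 and 6 of 6 still passed, and without the 5 arrays apart on the second component it was 0.59, again with 6 of 6, which argues against cortical tissue or that set of arrays as the whole cause. With the SD of the array as a covariate it was 0.53 and 5 of 6 passed. Ier2 went from 0.41 ± 0.07 to 0.39 ± 0.08 (adjusted p = 0.0718). The lowest share of its change that any of the 6 genes kept under that covariate was 0.73. None of 99 other splits of the continuous and water arrays gave a call, against 33 for the real one (1 of 100 splits as large, highest other 0). A count that large was thus unlikely by chance if the arrays are exchangeable between groups, which the labels do not settle. A response to ethanol or to its recent intake, and a difference in handling or time of day before death, may each account for the rise of those 6 and stay open as untested, since the time between the last access and death is not given in the sources used here.

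Homer1 probe sets moved in opposite directions with continuous ethanol. In 28 of 29 fits that left out 1 array both kept their calls, the exception being water replicate 5 (adjusted p = 0.0527 for the rising one), and the signs stayed opposite in all 29 fits, with changes nearest 0 of 0.72 and -0.73; whether a single array made the call of the rising one cannot be told apart on this test. Within groups, the rising probe set followed Fos at r = 0.660 (permutation p = 2.60e-04, adjusted p = 7.80e-04; rho = 0.626, p = 5.80e-04, adjusted p = 0.00174) and the falling one at r = 0.112 (permutation p = 0.580, adjusted p = 0.580; rho = 0.150, p = 0.456, adjusted p = 0.456), over 3 relations, the last between the probe sets at r = 0.315 (permutation p = 0.109, adjusted p = 0.163; rho = 0.397, p = 0.0423, adjusted p = 0.0634). The difference of 0.547 (95% bootstrap interval 0.0186 to 0.959) is consistent with separate transcript forms, but without the 2 arrays farthest in each the correlations were 0.453, 0.283 and 0.296 and the difference 0.170, so it rests in part on those arrays. By group the correlations with Fos were 0.770 and 0.735 in water, 0.858 and -0.0796 in continuous and 0.463 and -0.271 in limited arrays, so in water both followed Fos alike. Cross-hybridisation of a probe set to another transcript was not tested, since probe sequences were not used here.

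Endothelial and mural markers had a median of -0.15 with continuous ethanol. Without the 5 arrays of extreme leptomeningeal score it was -0.0446, with those markers as a covariate -0.0803, with the SD of the array as a covariate -0.0839 and without the 5 arrays apart on the second component -0.0747. Each lies closer than the SE of the list difference (0.0649) to -0.0739, the value set to decide between them, so neither carry-over of membranes and vessels in some dissections nor the spread of array values can be told apart from a change in vessel genes. A response of vessels to continuous ethanol may remain as another explanation.

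For the 3 groups 1 of 100 splits gave as many calls (18, highest other 1), so that count was unlikely by chance if the arrays are exchangeable between groups. For limited minus continuous it was 1 of 100 (1, highest other 0), but a single call is little to set against splits, and it was lost under 5 of 15 alternatives and with 1 array left out in several fits (0 to 3 calls), so no conclusion is drawn. The change of that Homer1 probe set stayed between 0.55 and 0.72 under those alternatives. For limited minus water the splits test nothing, since with 0 calls every split gives as many (100 of 100, highest other 2). For the lists called by camera at the preset correlation chance could not be excluded in any comparison. As many or more were called in 36 of 100 splits for continuous minus water (9, highest other 18), in 6 of 100 for limited minus water (12, highest other 15) and in 47 of 100 for limited minus continuous (6, highest other 18).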

How the results depend on the processing

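The array SD, cortical and leptomeningeal covariates, the fits without or blocking the 5 arrays apart, those without arrays of extreme leptomeningeal score and the fits that left out 1 array were chosen only after the data were seen. With continuous ethanol, Fos (0.57 to 0.87), Nr4a1 (0.64 to 0.78), Arc (0.58 to 0.69), Junb (0.32 to 0.38), Gadd45g (0.32 to 0.39) and the falling Homer1 probe set (-0.82 to -0.73) kept their calls under all 15 alternatives run for them, and none of the called genes reversed. Among those that lost calls, Nat8f3 (-0.23 to -0.20), Tgif1 (0.26 to 0.29) and the dimmer Dusp1 probe set (0.48 to 0.65) moved little toward 0. Psmc6 (0.18 to 0.28), Slc2a1 (-0.23 to -0.14) and Adgrl4 (-0.38 to -0.25) moved more. The count of 33 for continuous minus water was 20 with 1 probe set per gene (17 shared), where probe sets without a single symbol and dimmer ones of a gene, among them both called Homer1 probe sets, were not tested. It was 11 with the array SD as a covariate, 21 without the arrays of extreme leptomeningeal score, 12 without the 5 arrays apart and 14 with those as a block (fewer arrays in the fits that left some out), with 11, 18, 12 and 14 shared. Counts within a factor of 1.5 of 33 included 23 with the beta-actin and GAPDH covariate (22 shared), 29 with only the 2 groups compared (21 shared) and 48 with array weights (26 shared). The count of limited minus water was 1 instead of 0 with array weights. That of limited minus continuous was 0 instead of 1 with the beta-actin and GAPDH covariate, 1 probe set per gene (where the called probe set was not tested), the array SD, and the 5 arrays apart left out or blocked, and 2 with the cortical or leptomeningeal covariate. The count over 3 groups was 10 instead of 18 with the array SD. The correlation of both schedules fell from 0.609 to 0.0670 with split water arrays, by construction without shared controls. The oligodendrocyte list turned to a median of 0.0428 (adjusted p = 0.0480) under array weights. Elsewhere the cause was not tested. Leaving out 1 array gave 18 to 94 calls for continuous minus water, 0 to 0 for limited minus water, 0 to 3 for limited minus continuous and 10 to 22 over the 3 groups. The first was 18 without water replicate 5, 59 without water replicate 8, 94 without water replicate 4 and 66 without limited replicate 6, and 17 of the 33 passed in all 29 fits, 8 higher and 9 lower. Of the calls of lists at the preset correlation, 0 of 9, 0 of 12 and 0 of 6 kept their side under all alternatives, and 3, 3 and 0 did when the estimated correlation and the exact test are set aside.

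With the replicate number as a block, the counts were 28 for continuous minus water (22 shared), 0 for limited minus water, 0 for limited minus continuous and 16 over the 3 groups. The labels do not state that the numbers pair the samples, and the values do not settle it. In their deviations, 12 of 28 pairs of arrays with the same number correlated above 0.1 (-0.243 to 0.343), and 2 of 29 arrays correlated best with an array of their own number. The median was 0.0778 for pairs of the same number and -0.0115 for pairs of different number and group. The number of arrays limits precision, and dim probe sets were left out since their signal lies near background; the count was 33 with no filter and 44 with a stricter one.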

Other observations

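The tests of rapid against delayed activity genes and the leptomeningeal markers described here were chosen only after the data had been seen, while the other values come from lists fixed in advance.

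Each gene of a list was judged on its brightest probe set. With continuous ethanol against water, adjusted over all probe sets, 0 members passed in the lists of glutamate (34 measured, median 0.03), GABA (18, 0.01), neuropeptides and opioids (33, 0.01), serotonin, acetylcholine and adrenergic receptors (19, 0.03), synaptic vesicle release (37, 0.00) and ion channels (52, -0.00), and adjusted over each list alone 0 passed as well. Dimmer probe sets of Homer1, a member of the glutamate list, did pass, as given above. Crh, the stress peptide corticotropin-releasing hormone, had the smallest p of its list (0.31 ± 0.10, adjusted p = 0.168), followed by the receptor gene Npy1r (0.13 ± 0.05, adjusted p = 0.221). The list of neurotrophin and MAP kinase genes (36, -0.01) had 0 as well. In the circadian list (20, -0.01) Per2, a clock gene that is also induced by glucocorticoids, missed the threshold (-0.23 ± 0.05, adjusted p = 0.0547) and fell adjusted over the list alone (adjusted p = 0.00182). In the innate immune list (38, -0.02) the interferon-induced Mx2 missed it (0.27 ± 0.06, adjusted p = 0.0625) and rose adjusted over the list alone (adjusted p = 0.00569).

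In the glycolysis list of that comparison (25, 0.03) 1 member fell, Slc2a1, and adjusted over the list alone Pfkfb2 rose (0.15 ± 0.05, adjusted p = 0.0274). The lists of ethanol and aldehyde metabolism (19, 0.00), antioxidant defence (44, 0.00), ribosomal proteins (38, 0.00) and chromatin regulators (45, 0.01) had 0 members past the threshold either way. In the cytoskeleton list (46, 0.04) Tubb2b (0.14 ± 0.04, adjusted p = 0.0445) and among oligodendrocyte precursor markers (8, 0.03) Lhfpl3 (0.32 ± 0.10, adjusted p = 0.0224) rose adjusted over the list alone. Markers of interneurons (10, 0.08), cortical (12, 0.03) and septal neurons (6, -0.04), astrocytes (14, -0.02), oligodendrocytes (17, -0.01), microglia (15, -0.01), choroid plexus (8, -0.03) and blood (3, -0.18) had 0 members past it either way. All 16 leptomeningeal markers had lower means in both ethanol groups than in water and none passed, with Igf2 at -0.48 (adjusted p = 0.335) and Col3a1 at -0.40 (adjusted p = 0.427) for continuous ethanol.

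A hypothesis is that the rise of the 6 immediate early genes with continuous ethanol reflects activity shortly before death, in which case rapidly induced genes may rise more than delayed ones. Over 16 rapid genes, such as Fos, Arc and Junb, the mean differed by 0.27 between continuous and water arrays (exact permutation p = 3.90e-04, adjusted p = 0.00351), and over 16 delayed ones, such as Vgf, Scg2 and Bdnf, by 0.07 (exact p = 0.203, adjusted p = 0.228). The delayed genes include Plk2, Nr4a2, Nr4a3, Per1, Klf10, Ptgs2, Sik1 and Fosl2 of the fixed immediate early list. The contrast is thus partly between members of that list. The gap of 0.20 (exact p = 0.00448, adjusted p = 0.0202 over 9 tests) is no test of the hypothesis, since the rapid list holds the 6 genes whose rise prompted it. The same holds for limited minus water, where rapid genes differed by 0.17 (exact p = 0.00755, adjusted p = 0.0226) and rapid minus delayed by 0.09 (exact p = 0.0930, adjusted p = 0.139), and for limited minus continuous, where rapid minus delayed differed by -0.11 (exact p = 0.0207, adjusted p = 0.0465). For continuous minus water the 10 other rapid genes ran from Klf2 (0.36), Klf4 (0.30), Egr2 (0.21), Egr4 (0.14) and Jun (0.14) over Egr1 (0.07), Fosb (0.03) and Zfp36 (-0.00) to Egr3 (-0.13) and Ier3 (-0.21), none past the threshold on these probe sets. Their mean differed by 0.09 (exact p = 0.137, adjusted p = 0.622), and minus the delayed genes by 0.02 (exact p = 0.713, adjusted p = 0.713 over 6 tests). Without the called genes the gap for limited minus water was -0.02 (exact p = 0.696, adjusted p = 0.713) and for limited minus continuous -0.05 (exact p = 0.311, adjusted p = 0.622). The 10 other genes were kept because they had not passed in continuous minus water, which tilts them toward a small rise. The hypothesis stays open, since their values give it no support but cannot count against it.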
